A study of Homo sapiens with 3 samples.

How the data were processed

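The data were single-cell gene expression profiles from the root, the ascending segment and the arch of the human thoracic aorta, with 1 library per segment. Per the labels' protocols, tissue was digested to single cells and viable cells were sorted before droplet capture and 3-prime library preparation, so that all shares of cells follow that sort. The deposited files held, per the file headers, raw UMI counts per gene and barcode written by Cell Ranger 5.0.1, aligned to the human genome GRCh38. Seurat 4.3 is named in the submitters' processing notes with no role, and the annotation release used for counting is not given in the sources used here. No cell annotation was used here, so every cell class below was rebuilt and a difference from the study can come from rebuilt names. Gene positions were taken from GENCODE release 29 (GRCh38), matched by gene identifier. The files held 1212 root, 3148 ascending and 2020 arch barcodes, the numbers the labels give before filtering.

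Each library was filtered to barcodes with at least 500 genes and at most 10% mitochondrial UMIs, which left 1060 of 1212 root, 2528 of 3148 ascending and 1741 of 2020 arch barcodes. Doublets were removed by taking the highest Scrublet scores at a rate of 0.8% per 1000 cells of each library, which took 9 root, 51 ascending and 24 arch cells, 1.58% in all. This left 1051, 2477 and 1717 cells, against 1084, 2464 and 1768 that the labels give after the authors' own filter, which was not rebuilt. The kept cells had medians of 2580, 2690 and 3116 UMIs and totals of 3389843, 10803792 and 7160097 UMIs. Counts were scaled to 10000 per cell, and 2000 variable genes, 30 principal components and 15 neighbours were used for Leiden clustering at resolution 0.5 of the 3 libraries together. A cluster was called like a type when at least 3 markers of 1 of 19 fixed classes were among its leading 100 genes with no tie, and the leading 10 did not hold more markers of another class. The score for naming was changed from a pooled to a within-library fold after a T cell cluster was led by hemoglobin genes. No cluster was first named smooth muscle, so the stromal cluster was clustered again on its own, a step chosen after seeing the data.

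UMIs were summed per class and library and given as CPM with exact Poisson intervals, and shares with exact binomial (Clopper-Pearson) intervals. Ratios of 2 libraries have conditional exact binomial intervals. These cover counting error only. A gene was measured in a pair with at least 50 UMIs over both libraries, and a pseudocount of 1 CPM was used on the log2 scale. A ratio against 0 UMIs is a lower bound against a floor of 3 UMIs over the class. Median log2 ratios over all measured genes were 0.02, 0.08 and -0.08 in T cell-like cells for root over arch, root over ascending and ascending over arch. In SMC-like cells they were 0.42, 0.42 and 0.05, over 174, 146 and 236 genes.

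The rule for named genes was written before the data were examined. Measured genes were ranked by the bound of the 95% interval of their ratio nearest to 1, and the first 12 in each direction were named for SMC-like root versus arch, 8 for the other SMC-like pairs and 5 for other classes. Mitochondrial and ribosomal protein genes, antigen receptor segments, genes with clone-based names and sex-linked markers were left out by name. Genes were also left out when all other cells of the library where the gene was higher held it at over 5 times the CPM, which leaves it open to free RNA. In T cell-like cells for root versus arch these steps left out 366 and 96 of 7949 genes. The highest and lowest member of each described list was also named. Some genes that the rule picked are not reported here. The same rule for the other pairs of T cell-like, NK-like and macrophage-like cells, and a minimum of 30 rather than 50 cells for fibroblast-like cells, were added after seeing the data.

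There were 21 gene lists fixed before the data were examined and 11 lists of immune cell states added after the cell types were seen and before the segments were compared. A list needed 5 measured genes, and its members were counted as higher or lower from 1.5-fold apart. Its median log2 ratio has an interval from 1000 Poisson draws and a percentile among 10000 random lists of the same size matched on mean expression. The percentile describes these libraries and tests nothing. The text describes the contractile list in SMC-like cells, heat shock in the 3 large classes, the inflammatory and NF-kB list, and each list with a median of at least 1.5-fold in the outer 5% of its random lists. Smaller medians of the immediate early and dissociation, TGF-beta response and a few other fixed lists are given beside these where they bear on them, chosen after they were seen. That rule, and the choice of the list that stands first in each class, were set after the medians and their changes of sign had been seen. The remaining 180 medians covered further programmes, and 5 of them met the same size rule, all 5 in fibroblast-like cells of the root, which had 14 cells. In SMC-like cells, summed CPM was given for lists with too few measured members. The position of the ascending aorta was its log2 CPM on the line from arch to root, for genes with an interval bound of at least 1.5-fold between root and arch.

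Gene ratios and list medians were tested on simulated Poisson counts with the sizes of the T cell-like, NK-like, macrophage-like and SMC-like classes. These draws follow the model behind the intervals. The coverage therefore checks the calculation only, and does not cover differences between cells. Shares, positions and correlations were not tested in this way. For root over arch, intervals held the simulated value for 96.1% of 7744 unchanged genes in T cell-like cells, 96.2% of 3539 in NK-like cells, 95.7% of 6702 in macrophage-like cells and 97.8% of 93 in SMC-like cells. A simulated log2 change of 1 passed the 1.5-fold bound for 44.8% of 105 genes in T cell-like cells and 13.0% of 46 in SMC-like cells, and a change of 2 for 98.9% of 92 and 86.1% of 36. The alternatives were other cell filters, no doublet removal, a finer clustering, clustering of each library alone, median-of-ratios scaling, totals without mitochondrial and ribosomal protein genes, the mean of each cell's own CPM, cells thinned to 1000 UMIs, other count minimums and a larger pseudocount. Thinning left out 5 root, 10 ascending and 4 arch T cell-like cells, 7, 7 and 9 NK-like cells, 0, 1 and 7 macrophage-like cells, and no SMC-like cell. The alternatives were planned for SMC-like cells and shares, and their use in other classes was added. Removal of cells with at least 3 hemoglobin UMIs and the use of single clusters were added after seeing the data. Levels of sex-linked genes and of antigen receptor segments were not used here. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.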

Results

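Single-cell RNA profiles were collected from 3 segments of the human thoracic aorta: the root, where the vessel leaves the heart, the ascending aorta, and the arch. Each segment was 1 library of sorted single viable cells, so the segment and the library cannot be told apart, and the labels do not explain whether the segments came from the same donor. The title of the series names aortic smooth muscle cells of cardiac and of neural crest origin and disrupted TGF-beta signalling. The comparisons therefore ask how smooth muscle cells, and the other cells caught beside them, differed between segments. The root held 1212 barcodes and 3631978 unique molecular identifiers (UMIs, each counting 1 captured transcript), the ascending aorta 3148 barcodes and 11812423 UMIs, and the arch 2020 barcodes and 7717817 UMIs. The median barcode held 2486.5 UMIs in the root, 2325.5 in the ascending aorta and 2968 in the arch. With 1 library per segment there was no test and no p-value. Intervals are 95% intervals that cover counting error only. Those of gene levels and ratios treat each UMI as independent and leave out differences between cells. A difference outside them can therefore rest on few cells, and separates these libraries at most, not necessarily these segments.

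Immune cells made up nearly all of the cells in each segment, and the ascending aorta alone held many neutrophil-like and related myeloid cells. After filtering and doublet removal, 1051 root, 2477 ascending and 1717 arch cells remained. Leukocyte classes together with the unnamed cluster 10 held 97.53% of root cells (exact binomial interval 96.4 to 98.4), 97.4% of ascending cells (96.7 to 98.0) and 96.2% of arch cells (95.2 to 97.1). T cell-like cells were the commonest class, with 60.1% of root cells (57.1 to 63.1), 35.6% of ascending cells (33.7 to 37.5) and 66.6% of arch cells (64.3 to 68.8). Neutrophil-like cells, led by FCGR3B and CXCR2, were 1.52% of root cells, 16.8% of ascending cells and 0.408% of arch cells. Cluster 10, led by SERPINB2, FCN1, LYZ and VCAN, genes known from blood monocytes, stayed unnamed because it had under 3 markers of any class among its leading genes. It held 9 root, 653 ascending and 3 arch cells. Together these cells were 2.38% of the root library (1.55 to 3.49), 43.2% of the ascending library (41.2 to 45.1) and 0.582% of the arch library (0.280 to 1.07). With 1 library per segment, a cluster found mostly in 1 library can be that library and not a cell type.

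**Figure D1:**
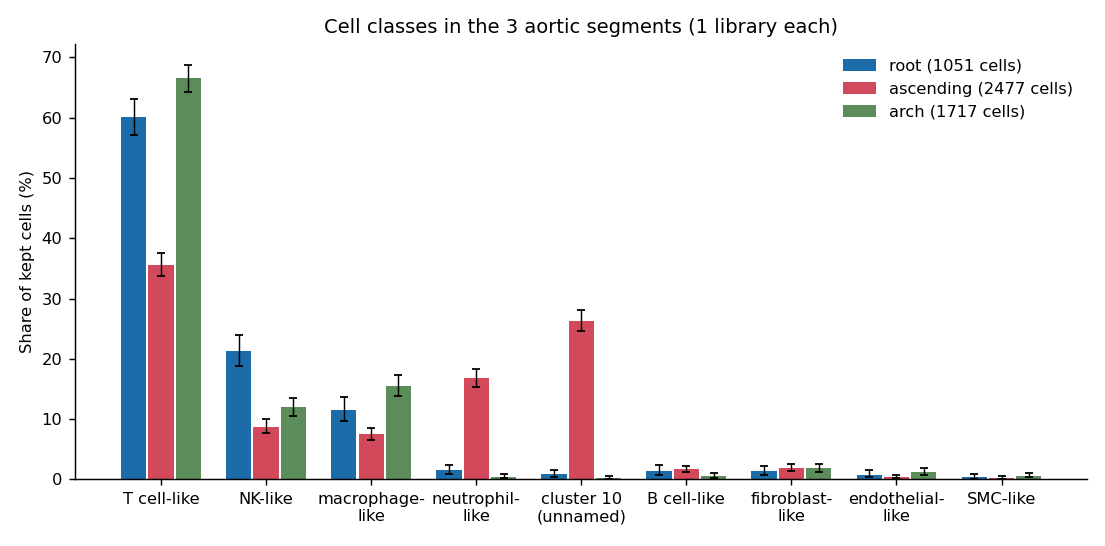
Share of kept cells (%) in each cell class for the root (1051 cells), ascending (2477 cells) and arch (1717 cells) libraries; bars are shares and whiskers are exact binomial 95% intervals. Neutrophil-like cells and cluster 10 stand out in the ascending library, and smooth muscle cell-like (SMC-like), fibroblast-like and endothelial-like cells are scarce in all 3.

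Outside the neutrophil-like cells and cluster 10, T cell-like cells held 61.6% of the root (58.5 to 64.6), 62.6% of the ascending aorta (60.0 to 65.1) and 67.0% of the arch (64.7 to 69.2). NK-like cells, the natural killer lymphocytes, were highest in the root at 21.8% (19.3 to 24.5), against 15.4% in the ascending aorta (13.6 to 17.4) and 12.01% in the arch (10.5 to 13.6). Macrophage-like cells were 11.8% (9.88 to 13.9), 13.1% (11.4 to 15.02) and 15.6% (13.9 to 17.5) in the same order. B cell-like cells were 1.46% (0.821 to 2.40), 2.91% (2.10 to 3.93) and 0.586% (0.281 to 1.07). These shares depend on the clustering: no B cell-like cluster was found with looser filters, nor in the root or arch clustered alone, and NK-like cells numbered 147 of 1051, 135 of 2477 and 108 of 1717 when each library was clustered alone, and 42 of 549, 32 of 1089 and 28 of 947 with at least 1000 genes and at most 5% mitochondrial UMIs. Cells of the vessel wall were few: smooth muscle-like, fibroblast-like and endothelial-like cells together held 2.47% of root cells (1.62 to 3.60), 2.62% of ascending cells (2.03 to 3.33) and 3.79% of arch cells (2.93 to 4.80). SMC-like cells numbered 4 in the root, 6 in the ascending aorta and 11 in the arch. Fibroblast-like cells numbered 14, 48 and 32, and endothelial-like cells 8, 11 and 22. All shares follow a digestion and a sort for single viable cells, which can set them, and free RNA in the droplets can blur the classes.

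The few SMC-like cells of the root and of the arch differed in single genes, among them JUN, MT1X, PLCG2 and RGS5. JUN, part of the AP-1 transcription factor that is induced by stress, was at 3593 CPM (counts of the gene scaled to the same total in every class and library) in the root and 146 in the arch, 24.6-fold higher in the root (11.5 to 60.1). MT1X, a metal-binding metallothionein, was 9.03-fold higher in the root (4.89 to 17.4), and the chaperones HSP90AA1 and HSPB1 were 4.68-fold (2.79 to 7.90) and 4.17-fold (2.34 to 7.43) higher. The other 8 genes named for the root were HSP90AB1, ARID5B, FTL, PALLD, LGALS1, CALM2, TPT1 and MYL6, with ratios from 1.51 to 2.94. Higher in the arch were PLCG2, a phospholipase of immune receptor signalling, at 4494 against 147 CPM (30.6-fold, 8.39 to 254, from 246 and 2 UMIs), RGS5, a regulator of G protein signalling typical of pericytes (5.68-fold, 2.36 to 17.8), and STEAP4, a metalloreductase (21.2-fold, 3.70 to 846). APOE, an apolipoprotein, had 93 UMIs in the arch and 0 in the root, at least 7.72-fold higher against a floor of 3 UMIs. S100A4, MYH9, SPARCL1, TIMP3, FILIP1L, CRIP1, MALAT1 and B2M were also higher in the arch, by 1.43-fold to 10.3-fold. RGS5 and STEAP4 belong to the pericyte markers, so a different share of pericyte-like cells among these few cells is not separated from a change in expression.

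The contractile list, fixed before the data were examined, had a lower root to arch ratio than the median measured gene. Its own interval spans 0, and the median of all genes depended on the count minimum. Over 11 measured members the median log2 ratio of root to arch was -0.17 (-0.47 to 0.01), at percentile 7.22 of 10000 random lists matched on expression. All 174 measured genes had a median of 0.42, or 0.08 with at least 20 UMIs and -0.10 with at least 200. Of the 174, 83 were of the kinds left out by name, such as mitochondrial and ribosomal protein genes. For root over ascending these were 80 of 146. The medians of all genes and the random lists include them. Scaling moved all genes alike: the list and all genes had medians of -0.80 and -0.20 with median-of-ratios, and -0.00 and 0.59 with totals without mitochondrial and ribosomal protein genes. With cells thinned to the same depth they were -0.49 and -0.09. ACTA2, smooth muscle alpha-actin (ENSG00000107796, protein-coding, GRCh38 chromosome 10, 88935074 to 88991339), was at 2933 CPM in the root (2095 to 3994), 3218 in the ascending aorta (2686 to 3823) and 4951 in the arch (4379 to 5576). MYH11, the smooth muscle myosin heavy chain, was at 3006, 3916 and 4329 CPM, and TAGLN, an actin-binding protein of smooth muscle, at 9238, 12696 and 9919. The root value rests on 13639 UMIs from 4 cells, against 40092 from 6 cells and 54741 from 11. With a stricter filter of at least 1000 genes and at most 5% mitochondrial UMIs, the class became a stromal cluster of 8, 15 and 19 cells, the contractile median was -1.54, and most of the genes named above changed direction: JUN, MT1X, HSP90AA1, HSP90AB1, ARID5B, FTL, PALLD, APOE, STEAP4, S100A4, SPARCL1, FILIP1L and B2M.

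**Figure D2:**
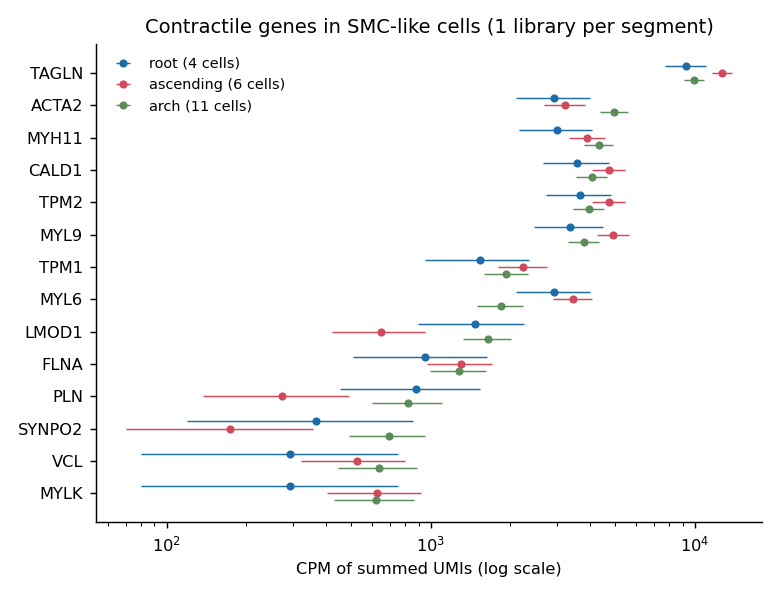
CPM of summed UMIs (log scale) of 14 contractile genes in SMC-like cells of the root (4 cells), ascending aorta (6 cells) and arch (11 cells); points are CPM and whiskers are exact Poisson 95% intervals. ACTA2 is at 2933, 3218 and 4951 CPM, and MYH11 intervals overlap between all 3 segments.

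Against the ascending aorta, SMC-like cells of the root had lower MT2A, MT1A and MT1M, while the related MT1X was at 2639 and 2220 CPM. MT2A (ENSG00000125148, protein-coding, GRCh38 chromosome 16, 56608199 to 56609497) was at 1393 CPM in the root and 11199 in the ascending aorta, 8.04-fold higher in the latter (5.09 to 13.5). MT1A was 6.35-fold (2.83 to 17.7) and MT1M 3.78-fold (1.91 to 8.51) higher in the ascending aorta. SPARCL1, IGFBP7, ADIRF, MALAT1 and TAGLN were higher in the ascending aorta by 1.34-fold to 2.57-fold. Higher in the root were the early response genes ATF3 (2.61-fold, 1.44 to 4.70), FOS (1.99-fold, 1.35 to 2.91) and JUN (1.92-fold, 1.31 to 2.79), the chaperones HSPA1A, HSPB1 and HSP90AA1 (1.66-fold to 2.18-fold), the ferritin light chain FTL (2.499-fold) and IGFBP5 (1.70-fold). The 9 measured contractile genes had a median log2 ratio of -0.40 (-0.62 to -0.18), at percentile 0.385, and none was 1.5-fold apart; the median was -0.92 with median-of-ratios scaling and -1.75 under the stricter filter, where all genes had medians of -0.10 and -0.04. FTL, ATF3, IGFBP5, SPARCL1 and IGFBP7 changed direction under the stricter filter, and 45.2% of the TAGLN UMIs of the root came from 1 of its 4 cells.

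Between the ascending aorta and the arch, SMC-like cells differed in metallothionein genes, FOS, JUN, STEAP4, FILIP1L and PLCG2, among others. MT1A was at 2794 CPM in ascending SMC-like cells and 36.5 in arch cells (76.5-fold, 20.7 to 639), MT1M was 27.3-fold (11.3 to 85.9), MT2A 12.8-fold (9.47 to 17.6) and MT1X 7.59-fold (4.43 to 13.9) higher in the ascending aorta. FOS was 96.9-fold (16.8 to 3882, from 71 and 1 UMIs), JUN 12.8-fold (6.17 to 30.7), GADD45B, a stress-response gene, 12.3-fold (5.29 to 35.0) and NAMPT, an enzyme of NAD synthesis, 8.39-fold (3.74 to 22.1) higher. STEAP4 had 85 UMIs in the arch and 0 in the ascending aorta, at least 20.8-fold higher in the arch. PLCG2 was 10.01-fold (6.20 to 17.2), RGS5 3.98-fold (2.48 to 6.67) and APOE 4.87-fold (2.76 to 9.24) higher in the arch, as were FILIP1L, MYH9, MGP and the protease inhibitor TIMP3, by 3.35-fold to 36.3-fold. Over 13 contractile genes the median log2 ratio was 0.02 (-0.17 to 0.27), with 1 gene at least 1.5-fold higher in the ascending aorta and 3 higher in the arch; MYL6 was 1.88-fold higher in the ascending aorta, while PLN, the sarcoplasmic calcium pump regulator phospholamban, was 3.00-fold higher in the arch. The metallothionein genes are close relatives, and counts split between them are uncertain. FOS, JUN, GADD45B and STEAP4 changed direction under the stricter filter.

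The lists tied to embryonic origin were counted in few UMIs in SMC-like cells. Transcription factors of the cardiac and second heart field summed to 6 UMIs in the root, 26 in the ascending aorta and 51 in the arch, or 440 CPM (161 to 958), 649 (424 to 950) and 932 (694 to 1225). Those of the neural crest summed to 22, 41 and 103 UMIs, or 1613 CPM (1011 to 2442), 1023 (734 to 1387) and 1882 (1536 to 2282). The HOX genes, which mark position along the body, summed to 1, 1 and 5 UMIs. Collagens were at 1173 CPM (671 to 1905), 2694 (2210 to 3252) and 4147 (3625 to 4723), and elastic fibre and microfibril genes at 660 (302 to 1253), 549 (344 to 831) and 603 (415 to 847). Genes of heritable thoracic aortic disease, which include ACTA2 and MYH11, summed to 7699 CPM (6297 to 9320), 10326 (9355 to 11371) and 13043 (12104 to 14036). These lists had too few measured members for a median in every pair, and their sums are dominated by their most abundant genes.

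TGF-beta pathway genes were barely counted in SMC-like cells. TGFBR2, the type II receptor, had 3 UMIs in the root (220 CPM, 45.4 to 643), 6 in the ascending aorta (150 CPM, 54.9 to 326) and 9 in the arch (164 CPM, 75.2 to 312). TGFB1 had 0, 1 and 1 UMIs, TGFB3 0, 1 and 2, TGFBR1 0, 0 and 2, SMAD3 1, 1 and 0, and TGFB2 0 in all 3; a count of 0 has an upper bound of 270 CPM in the root, 92.0 in the ascending aorta and 67.4 in the arch. A difference between segments was not detectable at this depth. T cell-like cells held the ligand TGFB1 at 312 CPM in the root (286 to 340), 303 in the ascending aorta (281 to 327) and 345 in the arch (327 to 365). Macrophage-like cells held TGFB1 at 103 CPM (82.8 to 127), 96.2 (80.1 to 115) and 161 (145 to 178). SMAD3, the intracellular signal carrier, was at 50.2 CPM (40.0 to 62.2), 18.2 (13.1 to 24.7) and 42.6 (36.1 to 49.9) in T cell-like cells. Fibroblast-like cells held TGFBR2 at 545 CPM (365 to 783), 533 (452 to 625) and 734 (620 to 862). The fixed TGF-beta response list was lower than in the arch by under 1.5-fold in T cell-like cells (median log2 -0.31 in the root, percentile 0.1, and -0.36 in the ascending aorta, percentile 0.57) and in macrophage-like cells (-0.46 in both, percentiles 0.365 and 0.55). It was -0.12 in both for NK-like cells, inside the central 95% of random lists.

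For genes that separated root from arch in SMC-like cells, the ascending aorta lay nearer the root at the filter used here, but not at a stricter one. On a scale where the arch is 0 and the root is 1, the median position of the ascending aorta was 0.76 over 5 genes higher in the root and 0.67 over 9 genes higher in the arch, 3 of which lay beyond the root. Under the stricter filter these were 0.052 and 0.107, next to the arch, and with thinned cells the latter was 1.18. At the main filter, the 5 genes higher in the root included JUN, MT1X and the chaperones HSP90AA1 and HSPB1, from 4 root cells. The position over them need not describe smooth muscle identity. The same measure in other classes, computed after the classes were known, was 0.85 over 20 genes and 0.50 over 11 genes in T cell-like cells, 0.84 over 31 and 0.54 over 5 in NK-like cells, and 0.54 over 101 and 0.58 over 123 in macrophage-like cells. Fibroblast-like cells, with 14 cells in the root, went the other way, at -0.09 over 33 genes and 0.22 over 70. Across genes, which are not independent replicates, Pearson's r of the root to arch ratios of SMC-like cells was -0.10 and Spearman's rho -0.02 with T cell-like cells (58 genes), 0.23 and 0.25 with NK-like cells (50 genes), -0.15 and -0.16 with macrophage-like cells (65 genes) and -0.39 and -0.17 with fibroblast-like cells (69 genes).

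In T cell-like cells, heat shock genes were highest in the arch and lowest in the ascending aorta. The ascending aorta was also below the arch in NK-like cells (median log2 -0.69) and in macrophage-like cells (-0.45). That direction was therefore not particular to T cells, and a shift of the whole library is not separated from a change in them. In macrophage-like cells the root was lower still (-0.22 over the ascending aorta). Of 14 measured heat shock genes, chaperones that refold damaged protein, 13 were at least 1.5-fold lower in the ascending aorta than in the arch, with a median log2 ratio of -0.996 (-1.09 to -0.92) and percentile 0. HSPA1A, the inducible HSP70 (ENSG00000204389, protein-coding, GRCh38 chromosome 6, 31815464 to 31817946), was at 441 CPM in the root (410 to 475), 104 in the ascending aorta (91.4 to 118) and 637 in the arch (612 to 664), 6.11-fold higher in the arch than in the ascending aorta (5.34 to 7.02). HSPA1B (4.81-fold, 4.17 to 5.56), HSPH1 (3.00-fold, 2.77 to 3.25), HSP90AA1 (2.69-fold, 2.61 to 2.78) and SERPINH1, a collagen chaperone outside the list (5.51-fold, 3.02 to 10.99), moved in the same direction. HSPA1A and HSPA1B are near-identical copies, so their split is uncertain. The fixed list of immediate early and dissociation genes, which can mark handling, was also lower than in the arch, with T cell-like medians of -0.18 in the ascending aorta and -0.35 in the root, but was lower in the root than in the ascending aorta (-0.19), opposite to heat shock. Cluster 0, with CD8A and GZMK among its leading genes, held most T cell-like cells of the root (346) and arch (748), and cluster 1, with IL7R and CCR7, most of the ascending aorta (515).

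T cells of the ascending aorta had more of the genes of regulatory and of naive or central memory T cells than those of the arch. The added regulatory T cell list had 4 of 6 measured members at least 1.5-fold higher (median log2 0.82, 0.51 to 1.05, percentile 100). IL2RA, the interleukin-2 receptor alpha chain (ENSG00000134460, protein-coding, GRCh38 chromosome 10, 6010689 to 6062370), was at 102 CPM in the ascending aorta against 16.9 in the arch (6.07-fold, 4.56 to 8.19), and TIGIT, an inhibitory receptor, at 65.2 against 58.9. The naive and central memory list had 8 of 11 members at least 1.5-fold higher (median 0.64, 0.54 to 0.98). Among them was the chemokine receptor CCR7 (138 against 56.4 CPM), while the transcription factor TCF7 was at 93.2 against 118. Within cluster 0 alone that median was 0.05 and within cluster 1 alone 0.33. CH25H, which makes 25-hydroxycholesterol, was 6.82-fold higher in the ascending aorta (5.12 to 9.22). HBA1, HBB and HBA2 headed the genes named for the ascending aorta, at 82.5-fold, 36.7-fold and 32.7-fold, but 99.3% of its 20038 hemoglobin UMIs lay in 22 cells, and HBB and HBA2 changed direction when each library was clustered alone.

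Root T cell-like cells were between the other segments in heat shock genes and high in a migration receptor. Against the arch, 4 of 14 heat shock genes were at least 1.5-fold lower in the root and none higher (median log2 -0.40, -0.48 to -0.37, percentile 0); HSPA1B was 1.65-fold higher in the arch and HSPB1 1.07-fold. S1PR1, the receptor that guides lymphocytes out of tissue, was 2.96-fold higher in the root (2.01 to 4.39), and FRMD4B 2.55-fold (1.96 to 3.33). The arch was higher in FOSB, an AP-1 subunit (1.98-fold, 1.83 to 2.15), MYADM (2.29-fold, 1.99 to 2.65), the kinase AATK (3.24-fold, 1.76 to 6.52) and the zinc finger genes ZNF165 (3.93-fold, 2.30 to 7.23) and ZSCAN18 (3.08-fold, 1.89 to 5.28). HBB, HBA1 and HBA2 were 4.58-fold to 11.9-fold higher in the root, where 99.0% of 3760 hemoglobin UMIs lay in 4 cells; in the arch 92.2% of 858 lay in 2 cells.

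Compared with the ascending aorta, root T cell-like cells had 6 of 14 heat shock genes at least 1.5-fold higher and none lower (median log2 0.54, 0.48 to 0.67, percentile 100). HSPA1A was 4.23-fold (3.65 to 4.93), HSPA1B 2.92-fold (2.48 to 3.45) and SERPINH1 4.54-fold (2.34 to 9.51) higher, and HSPA5, a chaperone of the endoplasmic reticulum, 1.09-fold. XAF1, an interferon-induced gene, was 3.01-fold higher in the root (2.24 to 4.08), and PALM2-AKAP2, a read-through gene whose counts are uncertain, 3.91-fold. Regulatory T cell genes were lower in the root, with 4 of 6 at least 1.5-fold apart (median -0.81, -1.06 to -0.50, percentile 0) and IL2RA 3.03-fold higher in the ascending aorta. CH25H was 5.75-fold higher in the ascending aorta (3.97 to 8.59), and HIST1H1B, a linker histone of dividing cells, 5.56-fold, with 73.6% of its ascending UMIs in 1 cell. HBA2, HBA1 and HBB were 7.14-fold, 6.95-fold and 3.65-fold higher in the ascending aorta, with the same concentration in few cells, and all 3 changed direction when each library was clustered alone.

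NK-like cells of the root and ascending aorta had higher NF-kB response genes than those of the arch. Of 11 measured members of the inflammatory and NF-kB list, 7 were at least 1.5-fold higher in the root and none lower (median log2 0.86, 0.74 to 1.06, percentile 100). TNFAIP3, which shuts off NF-kB signalling (ENSG00000118503, protein-coding, GRCh38 chromosome 6, 137867188 to 137883312), was at 823 CPM in the root (751 to 900), 1209 in the ascending aorta (1118 to 1304) and 414 in the arch (362 to 472). NFKB2, an NF-kB subunit, was 2.90-fold higher in the root than in the arch, and SOD2, mitochondrial superoxide dismutase, was level at 61.5 CPM in both. The immediate early and dissociation list, which can mark handling, went the same way in NK-like cells, with medians of 0.32 in the root and 0.35 in the ascending aorta over the arch (percentile 99.93 in both). Interferon-induced IFIT3 (5.90-fold, 2.77 to 14.4) and MX2 (3.95-fold, 2.27 to 7.31) and the inhibitory receptor HAVCR2 (3.93-fold, 2.07 to 8.11) were higher in the root. The lymphocyte cytokine list was also higher in the root, with 3 of 6 members at least 1.5-fold apart (median 0.59, 0.38 to 0.75), led by the chemokine XCL1 (1.83-fold), with CCL3 lowest (1.17-fold). Higher in the arch were RCAN3 (2.56-fold, 1.69 to 3.93), CA5B, STRBP, ENTPD4 and RAB30-DT, by 2.36-fold to 3.44-fold. HBB was 120-fold higher in the root and HBA2 at least 22.7-fold, and 98.8% of the 1638 hemoglobin UMIs came from 1 cell; RAB30-DT shares its locus with a gene on the other strand, and its counts are uncertain.

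The ascending aorta exceeded the arch by at least 1.5-fold in 9 of 10 NF-kB list members in NK-like cells, and none was lower (median log2 1.09, 0.93 to 1.31, percentile 100). TNFAIP3 was 2.92-fold (2.51 to 3.40) and NFKB2 4.17-fold (2.30 to 8.10) higher, with CEBPD the least apart at 1.31-fold. CD83, an activation marker (5.54-fold, 3.498 to 9.17), RBBP8, a DNA repair factor (4.27-fold, 2.49 to 7.72), and IL1RL1, the receptor for interleukin-33 (14.6-fold, 5.41 to 55.4), were higher in the ascending aorta; IL1RL1 was counted in 10 of 217 ascending cells. Heat shock genes were lower in the ascending aorta, 8 of 13 by at least 1.5-fold (median -0.69, -0.85 to -0.57, percentile 0), with HSPA1A 3.38-fold (2.69 to 4.27) and HSPA1B 3.33-fold (2.40 to 4.70) higher in the arch. SRGAP3, RAB30-DT and EPHA1-AS1, an antisense gene whose counts are uncertain, were 4.23-fold to 5.74-fold higher in the arch.

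Root and ascending NK-like cells were closer to each other in NF-kB genes than either was to the arch. Cluster 3, led by XCL1 and KLRC1, held most NK-like cells of the root (150) and the ascending aorta (133). In the arch it held 103, against 102 in cluster 4, led by GZMB and GNLY. NK-like clusters were not compared alone, so another mix of them is not separated from a change in expression. The root to ascending median of the NF-kB list was -0.20 (-0.37 to -0.04) over 11 genes, and 1 was at least 1.5-fold lower in the root. Heat shock genes were higher in the root, 5 of 12 by at least 1.5-fold (median 0.57, 0.51 to 0.77), led by HSPA1B (2.91-fold); against the arch the root median was -0.07 (-0.15 to 0.04). The tissue residency list had 5 of 7 members at least 1.5-fold higher in the root (median 0.66, 0.46 to 0.81, percentile 100). Its members ran from CRTAM, an adhesion receptor (2.31-fold), to ITGAE, the integrin CD103, at 76.9 and 76.6 CPM. IFIT3 was 11.7-fold (4.299 to 44.7), MX2 4.18-fold (2.37 to 7.89) and HSPA6, a heat shock gene outside the list, 6.56-fold (2.95 to 17.2) higher in the root. FCGR3A, the Fc receptor CD16 of cytotoxic NK cells (2.35-fold, 1.503 to 3.75), IL1RL1 (2.58-fold), SIPA1L1 (2.43-fold) and EIF5A (2.23-fold) were higher in the ascending aorta. HBB and HBA2, 35.7-fold and 22.5-fold higher in the root, again rested on 1 cell, and without cells holding 3 or more hemoglobin UMIs the log2 ratio of HBB was -1.31.

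Macrophage-like cells of the root were rich in lipid-handling genes. All 10 genes of the added lipid-associated macrophage list were at least 1.5-fold higher in the root than in the arch (median log2 1.31, 1.21 to 1.53, percentile 100). SPP1, osteopontin (ENSG00000118785, protein-coding, GRCh38 chromosome 4, 87975650 to 87983426), was at 842 CPM in the root (782 to 906), 355 in the ascending aorta (323 to 389) and 165 in the arch (149 to 182), 5.11-fold higher in the root than in the arch, and CD9, a tetraspanin, was 1.71-fold higher. FABP4, a fatty acid carrier (ENSG00000170323, protein-coding, GRCh38 chromosome 8, 81478419 to 81483263), had 716 UMIs in 30 of 121 root cells and 0 in the arch, at least 653-fold higher against a floor of 3 UMIs. CD36, a scavenger receptor (ENSG00000135218, protein-coding, GRCh38 chromosome 7, 80369575 to 80679277), was 18.0-fold (11.7 to 28.9), SPARC, a matrix protein, 20.2-fold (9.60 to 48.9), TFPI, an inhibitor of blood clotting, 14.9-fold (8.66 to 27.2) and HMOX1, the heme-degrading enzyme heme oxygenase 1, 7.79-fold (6.81 to 8.94) higher in the root. Cluster 8 held most macrophage-like cells in all 3 segments (78, 138 and 191).

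Heat shock genes, MHC class II genes and some chemokines were higher in arch macrophage-like cells than in those of the root. The chemokines CCL4L2 and CCL3L1 were 4.13-fold (3.498 to 4.90) and 3.48-fold (2.97 to 4.09) higher; they are close copies of CCL4 and CCL3, and the split is uncertain. PDGFB, a growth factor for smooth muscle, was 3.82-fold (3.11 to 4.74), the junction protein CLDN1 6.58-fold (3.25 to 15.5) and ANK3 6.35-fold (3.14 to 15.01) higher. All 7 genes of the MHC class II list, which present antigen to T cells, were at least 1.5-fold higher in the arch (root over arch median -0.66, -0.90 to -0.63), from HLA-DRA (2.06-fold) to HLA-DMA (1.53-fold), while the broader list of interferon and antigen presentation, fixed beforehand, had a median of 0.17 (-0.09 to 0.27). Heat shock genes were at least 1.5-fold higher in the arch for 10 of 14 (median -0.66, -0.70 to -0.59). The immediate early and dissociation list was higher there too (median -0.53, percentile 0). So were 4 of 5 lymphocyte cytokine genes (median -0.87, -1.05 to -0.81), led by CCL5 (4.67-fold), while CCL20 was 2.08-fold higher in the root. The monocyte list was at least 1.5-fold higher in the root for 6 of 10 (median 0.95, 0.58 to 1.17). THBS1, thrombospondin 1, was 3.19-fold higher in the root, and the chemokine receptor CCR2 2.79-fold higher in the arch. When each library was clustered alone, 41 root cells remained macrophage-like, the median of all genes was -0.64, the monocyte and MHC class II medians changed direction, and the heat shock and lymphocyte cytokine medians were -2.96 and -7.85, or -2.75 and -4.12 with 0 counts set to the floor; within cluster 5 alone the MHC class II median was -0.07.

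**Figure D3:**
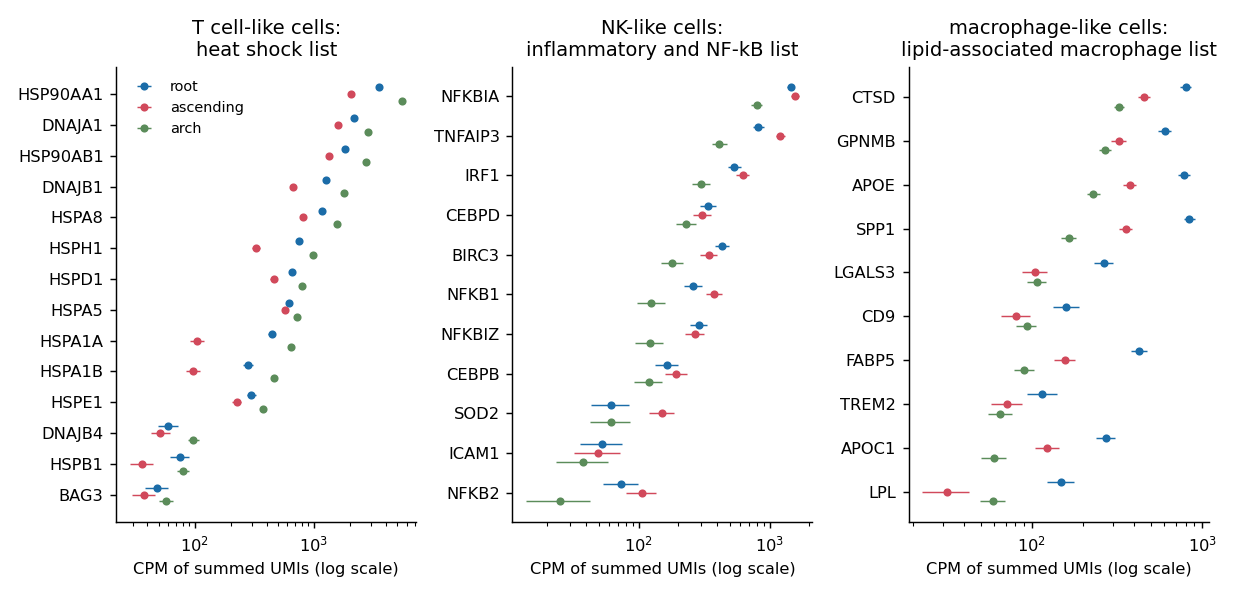
CPM of summed UMIs (log scale) per segment for heat shock genes in T cell-like cells, inflammatory and NF-kB genes in NK-like cells, and lipid-associated genes in macrophage-like cells; points are CPM and whiskers are exact Poisson 95% intervals. Heat shock genes sit lowest in the ascending aorta (HSPA1A 104 CPM against 637 in the arch), NF-kB genes lowest in the arch (TNFAIP3 414 CPM) and lipid-associated genes highest in the root (SPP1 842 CPM).

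Macrophage-like cells of the root also exceeded those of the ascending aorta in lipid handling. All 10 lipid-associated genes were at least 1.5-fold higher (median log2 1.09, 0.98 to 1.24, percentile 100), from LPL, lipoprotein lipase (4.68-fold, 3.27 to 6.83), to the lipid receptor TREM2 (1.61-fold). FABP4 was 23.2-fold (17.3 to 31.9), CD36 4.08-fold (3.01 to 5.60), SPARC 4.09-fold (2.47 to 7.002) and LIPA, lysosomal acid lipase, 2.83-fold (2.40 to 3.35) higher in the root. The ascending aorta was higher in HMOX1 (3.77-fold, 3.504 to 4.07), the glutathione synthesis gene GCLM (4.63-fold, 3.44 to 6.36), and the cytokines IL6 (11.8-fold, 3.83 to 59.1, from 54 and 3 UMIs) and IL7 (15.8-fold, 4.13 to 134, from 48 and 2 UMIs). AKAP12, a kinase anchor, had 72 UMIs in 3 ascending cells and 1 in the root (47.3-fold, 8.22 to 1892). The monocyte list was at least 1.5-fold lower in the root for 6 of 9 genes (median -0.87, -0.96 to -0.72). S100A8 was 3.05-fold higher in the ascending aorta and FCN1 1.24-fold higher in the root. MHC class II genes were lower in the root, 4 of 7 by at least 1.5-fold (median -0.60, -0.65 to -0.40), from CIITA, their master regulator (1.70-fold), to HLA-DMB (1.12-fold). The heat shock median was -0.22 (-0.27 to -0.17), with 2 of 14 genes at least 1.5-fold lower in the root. CD36 (-0.15) and the MHC class II median changed direction when each library was clustered alone, where the median of all genes was -0.47, so that CD36 stayed above the typical gene. The heat shock and monocyte medians were then -2.67 and -3.57, or -2.33 and -2.69 with 0 counts set to the floor.

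HMOX1 and 3 genes of glutathione and redox metabolism were among those most above the arch in ascending macrophage-like cells. HMOX1 (ENSG00000100292, protein-coding, GRCh38 chromosome 22, 35380361 to 35394214) was at 3681 CPM in the ascending aorta (3578 to 3787) and 125 in the arch (111 to 140), 29.4-fold higher in the ascending aorta (26.1 to 33.2). GCLM (11.96-fold, 8.94 to 16.3), the sulfiredoxin SRXN1 (13.2-fold, 6.30 to 32.1) and the cystine importer SLC7A11 (91.6-fold, 15.7 to 3687, from 51 and 1 UMIs) were higher too, as was AKAP12 (64.6-fold, 17.3 to 544), of which 68.1% of ascending UMIs came from 1 cell. The monocyte list was at least 1.5-fold higher for 7 of 10 genes and as much lower for none (median 1.62, 1.43 to 1.77, percentile 100). Its median was 0.80 with each library clustered alone. THBS1 was 5.92-fold higher, while CCR2 was 1.21-fold higher in the arch. Higher in the arch were EGR3, an early response transcription factor (4.69-fold, 3.77 to 5.89), PDGFB (4.01-fold, 3.37 to 4.81), the chemokine receptors CX3CR1 (5.47-fold, 2.94 to 11.3) and CXCR4 (3.27-fold, 2.77 to 3.87), and SFMBT2 (4.62-fold, 2.90 to 7.76). Lymphocyte cytokine genes were lower in the ascending aorta for 4 of 5 (median -0.91, -0.98 to -0.86), with CCL5 4.87-fold higher in the arch and CCL20 2.02-fold higher in the ascending aorta. Heat shock genes had a median of -0.45 (-0.51 to -0.41), with 4 of 14 at least 1.5-fold lower and 1 as much higher. The immediate early and dissociation list had a median of -0.43 (percentile 0). The lipid-associated median was 0.38 (0.27 to 0.51), with 4 of 10 at least 1.5-fold higher and LPL 1.86-fold higher in the arch. Neutrophil-like cells and cluster 10, which carry monocyte list genes, made up 43.2% of the ascending library, and whether free RNA from them adds to the monocyte list counts is left open.

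Fibroblast-like cells, compared between the 48 ascending and 32 arch cells with a class minimum of 30 cells chosen after the counts were known, differed in inflammatory genes and in single matrix genes. PTX3, a pattern recognition protein, had 307 UMIs in the ascending aorta and 0 in the arch, at least 72.5-fold higher. ADAMTS4, which cleaves proteoglycans (42.3-fold, 16.3 to 157), PAPPA, a protease that frees insulin-like growth factors (38.4-fold, 14.8 to 142), and MT1A (30.4-fold, 18.0 to 55.9) were higher in the ascending aorta, while the fixed matrix protease and inhibitor list had a median of only 0.22 (percentile 83.6). Smaller than 1.5-fold but in the outer 5% of random lists, 3 further fixed lists were lower in the ascending aorta: elastic fibre and microfibril (-0.51, -0.77 to -0.42), immediate early and dissociation (-0.50, -0.64 to -0.37) and TGF-beta response (-0.46, -0.75 to -0.29). POSTN, periostin, was at least 22.4-fold higher, with 92.6% of its UMIs in 1 cell. The inflammatory and NF-kB list had 7 of 13 members at least 1.5-fold higher and 1 as much lower (median log2 0.68, 0.22 to 0.87, percentile 99.4). CXCL3 was at 74 UMIs against 0, and IRF1 was 1.97-fold higher in the arch. Higher in the arch were CCN2, a TGF-beta and mechanical response gene (7.33-fold, 4.26 to 13.4), TSC22D3, induced by glucocorticoids (5.24-fold, 3.84 to 7.27), ITGB8 (at least 25.9-fold) and GPM6B and CDH19 (32.0-fold and 10.5-fold), markers fixed for Schwann cells and counted in 7 and 5 arch cells. Sub-cluster s3, with MT1A, MT1M and PAPPA among its leading genes, held 27 of the 48 ascending and 0 of the 32 arch cells, so a class-wide difference in those genes repeats that sub-cluster. Sub-cluster s0, led by DCN and COL1A2, held most arch cells (25). Of the fibroblast-like UMIs, s3 gave 193386 of 284924 in the ascending aorta, and s0 gave 188249 of 201725 in the arch. The comparison therefore largely sets s3 against s0. None of the gene and list differences above is separated from another mix of sub-clusters.

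The other gene lists, such as proliferation in T cell-like cells and matrix proteases in macrophage-like cells, stayed under 1.5-fold or within the central 95% of random lists in every class with enough cells. Of 180 further medians over all classes and pairs, 5 passed both bounds, and all 5 were in fibroblast-like cells compared with the 14 cells of the root.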

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

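The tests of removal by the cell filter, of blood carry-over, of hemoglobin exposure and of the limit set by FCN1 and FCGR3B were chosen only after the results were seen, as were the size bounds for a difference between cell classes.

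A neutrophil signal lay in barcodes that the comparisons of the kept cells left out. Of 620 ascending barcodes that failed the cell filter, 38.1% (34.2 to 42.0) held a UMI of FCGR3B or CXCR2, against 3.95% of 152 in the root and 1.08% of 279 in the arch.

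Opposite directions in 2 cell classes of the same segments marked 2 lists for a closer look. For root over arch, the inflammatory and NF-kB median log2 ratio was 0.86 in NK-like cells and -0.19 in macrophage-like cells, and the lymphocyte cytokine median was 0.59 and -0.87. With 1 library per segment the difference was not tested.

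Neutrophil-like cells and cluster 10 were found almost only in the ascending aorta. Removal by the cell filter used here does not explain it. Among all barcodes at most 2.23% in the root and arch (2.23% and 0.891%) held an FCGR3B or CXCR2 UMI, against 20.9% in the ascending aorta. Clustering all barcodes gave 22 root, 665 ascending and 3 arch cells like cluster 10. Every barcode in the files held at least 500 UMIs, so an earlier loss of cells with less RNA was not tested. Blood cells carried over with the ascending segment stay open: in T cell-like cells with under 3 hemoglobin UMIs, hemoglobin CPM was 2.82 times that of the next segment (62.0 against 22.0). Barcodes with at least 3 hemoglobin UMIs made up 2.72% of all root and 4.19% of all ascending barcodes, but 18.4% and 16.3% of those that failed the filter, so these do not decide it. Entry of these cells into the wall of that segment was not tested, and the 2 cannot be told apart with 1 library per segment.

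FABP4, CD36, SPARC and LPL were higher in root macrophage-like cells. Adipocytes in the digest are argued against by 0 UMIs of ADIPOQ, PLIN1, PLIN4 and CIDEC beside 716 of FABP4 (a limit of 0.419%). Free RNA is argued against by ratios of macrophage-like to T cell-like CPM in the root. These were at least 463 for FABP4, 102 for CD36, 38.1 for SPARC and 81.4 for LPL. They are lower bounds against a floor of 3 UMIs, since root T cell-like cells held 2 UMIs of FABP4 and 0 of CD36, SPARC and LPL. Doublets with endothelial cells are argued against by endothelial genes at 0.0939% of their level in endothelial-like cells. A lipid-handling macrophage state of this root library remains a hypothesis, with FABP4 in 7 of 43 cells of cluster 5 and 23 of 78 of cluster 8, and whether it belongs to the segment or the donor was not tested.

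HMOX1, GCLM, SRXN1 and SLC7A11, and the monocyte list, were higher in ascending macrophage-like cells than in arch. Another mix of the 2 macrophage-like clusters does not explain HMOX1, which was 11.9-fold (7.29 to 20.4) higher within cluster 5 and 30.6-fold within cluster 8. RNA from cluster 10 or neutrophil-like cells was to be excluded if each of HMOX1, GCLM, SRXN1 and SLC7A11 was lower there than in macrophage-like cells, which 2 genes narrowly missed (0.224, 0.820, 1.09 and 1.01 times), so its exclusion rests on the later limit: the FCN1 and FCGR3B levels allow such RNA to make up at most 4.74% of any of the 4. For the monocyte list as a whole it stays open, with a median of 3.34 times the macrophage-like CPM in those cells. FCN1 allows at most 4.68% of macrophage-like UMIs from cluster 10, and FCGR3B 0.0595% from neutrophil-like cells. That falls well short of the level of VCAN, EREG, CD300E, THBS1, CCR2 and CD14 (0.651 to 3.89 times). It does not for SERPINB2 (23.3 times). FCN1 (21.4 times) sets the limit and so meets it by definition, which leaves its source undecided. S100A8 and S100A9 (59.2 and 31.1 times) were not resolved by source. Exposure to hemoglobin stays open too, since hemoglobin CPM in macrophage-like cells was 4.601 times the arch value in the ascending aorta and ranked the 3 segments as HMOX1 did. That rank rests on 10 root, 41 ascending and 16 arch UMIs. T cell-like and NK-like cells with under 3 hemoglobin UMIs had the same order of segments, so it was not particular to macrophage-like cells and cannot show exposure.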

How the results depend on the processing

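No paired analysis was possible because each segment was 1 library. Planned tests covered SMC-like cells, cells kept and shares; all tests of gene and list values in other classes, with any filter, clustering or scaling, were chosen only after results were seen.

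The medians that stand first in the large immune classes kept their direction in every setting. Those lists were chosen after changes of sign had been seen, so this describes the chosen lists and is no test of stability. The ascending over arch heat shock median of T cell-like cells ranged from -1.03 to -0.92 and stayed within its main interval in all 16 settings; root over arch ranged from -0.49 to -0.39 and root over ascending from 0.44 to 0.65. The NK-like NF-kB median ranged from 0.75 to 1.12 for root over arch, 1.003 to 1.38 for ascending over arch and -0.26 to -0.12 for root over ascending. The lipid-associated median ranged from 0.86 to 1.61, 0.08 to 0.52 and 0.84 to 1.31 for root over arch, ascending over arch and root over ascending. Neutrophil-like cells and cluster 10 held 43.1% to 45.6% of the ascending aorta. The filter at 1000 genes and 5% mitochondrial UMIs gave 488 neutrophil-like and 0 cluster 10 cells there, against 416 and 653 at the main filter. A like share therefore need not hold the same cells. Of 1852 named-gene values, 1635 stayed within the main interval, 187 moved outside it and 30 changed direction. A change of direction was counted only where the main interval excluded 0. The contractile median for ascending over arch, whose interval spans 0, ranged from -0.18 to 0.60 and is not counted as such a change. Of 173 medians of the list that stands first in its class, 148 stayed and 25 moved, and of 268 medians of other described lists, 205 stayed, 60 moved and 3 changed direction. Of 72 shares of other classes 36 moved, and of 114 positions in other classes 38. Of 2374 medians of further lists, 54 changed sign from a main interval that excluded 0, none with a main size over 0.57. Other changes of sign were not counted. SMC-like cells limit the data: with 4, 6 and 11 cells the class can hold other cells under another filter. Scaling choices shifted all genes there at once, by -0.63 log2 for root over arch with median-of-ratios. No value could be given for SMC-like pairs with the root when each library was clustered alone, which left no SMC-like root cell, nor for many SMC-like genes when thinned or with a minimum of 200 UMIs. The cause of the changes below was not tested.

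With at least 1000 genes and at most 5% mitochondrial UMIs, 549 root, 1089 ascending and 947 arch cells were kept. Neutrophil-like cells and cluster 10 held 1.46% of the root and 0 of the arch, T cell-like cells 72.5% and 75.4%, and SMC-like cells 1.46%, 1.38% and 2.01% of root, ascending and arch. The NF-kB median of NK-like cells was 1.12 for root over arch and 1.38 for ascending over arch, the lipid-associated median 0.0812 for ascending over arch, and the contractile median -1.54, -1.75 and 0.60 for root over arch, root over ascending and ascending over arch. In SMC-like cells, root over arch, the log2 ratios were JUN -0.24, MT1X -0.90, HSP90AA1 -0.24, HSP90AB1 -1.37, ARID5B -0.88, FTL -0.74, PALLD -0.92, APOE 2.11, STEAP4 0.96, S100A4 0.78, SPARCL1 0.0078, FILIP1L 0.66 and B2M 0.25; root over ascending FTL -1.04, ATF3 -1.55, IGFBP5 -11.34 (0 root UMIs, so set by the pseudocount, and at least 38.0-fold lower against the floor), SPARCL1 0.73 and IGFBP7 1.17; ascending over arch FOS -0.0997, JUN -0.36, GADD45B -0.16 and STEAP4 2.28. The position of the ascending aorta was 0.052 over genes higher in the root and 0.107 over genes higher in the arch.

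With all barcodes, neutrophil-like cells and cluster 10 held 3.5% of the root, and T cell-like cells 55.1%, 30.8% and 58.6% of root, ascending and arch. With at least 200 genes and at most 20% mitochondrial UMIs, T cell-like cells held 55.1%, 31.8% and 60.4%, neutrophil-like cells and cluster 10 held 45.6% of the ascending aorta, and the lipid-associated median for root over ascending was 0.94. At resolution 1.0, T cell-like cells held 63.7% of the root and 71.3% of the arch.

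With each library clustered alone, neutrophil-like cells and cluster 10 held 0 of the root and 0 of the arch, SMC-like cells 0 of the root, and T cell-like cells 66.9% of the root and 38.6% of the ascending aorta. The T cell-like heat shock median for root over arch was -0.49. In T cell-like cells the log2 ratios for root over ascending were HBA2 2.76, HBA1 3.46 and HBB 4.66, and for ascending over arch HBB -1.47 and HBA2 -0.74. In macrophage-like cells, of which 41 root cells remained, all genes shifted by -0.63 for root over arch and -0.53 for root over ascending; the root over arch medians were lipid-associated 1.61, monocyte -2.66, MHC class II 0.37, heat shock -2.96 and lymphocyte cytokine -7.85; root over ascending, lipid-associated 1.31, MHC class II 0.80, monocyte -3.57, heat shock -2.67 and CD36 -0.15; and the ascending over arch monocyte median was 0.80. With 0 counts set to the floor, the root over arch monocyte, heat shock and lymphocyte cytokine medians were -1.14, -2.75 and -4.12. The root over ascending monocyte and heat shock medians were then -2.69 and -2.33.

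With median-of-ratios, the T cell-like heat shock median for root over ascending was 0.44 (0.48 with totals without mitochondrial and ribosomal protein genes), the contractile median -0.80 for root over arch and -0.92 for root over ascending, and TPT1 -0.033 for root over arch. With the mean of each cell's own CPM, the lipid-associated medians were 0.94, 0.96 and 0.17 for root over arch, root over ascending and ascending over arch. With cells thinned to 1000 UMIs they were 1.19, 1.30 and 0.13, the contractile median for root over arch was -0.49, and the position over genes higher in the arch was 1.18. Within macrophage-like cluster 5 they were 0.86, 0.84 and 0.0812, and within cluster 8 root over ascending was 0.96. Without cells holding 3 or more hemoglobin UMIs, HBB in NK-like cells for root over ascending was -1.31.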

Other observations

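All tests in this part were chosen only after the results were seen.

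Plasma cell-like cells numbered 6 in the root, 11 in the ascending aorta and 9 in the arch, and mast cell-like cells 2, 8 and 8. Fibroblast-like cells of the root, 14 in number and below the class minimum, had a collagen median log2 ratio of 1.76 (1.49 to 2.02) over the arch and 1.62 (1.35 to 1.88) over the ascending aorta, with 10 measured genes in each. In the same cells the immediate early and dissociation median was -0.62 over the arch, and the matrix protease and inhibitor median was -1.63 and the inflammatory and NF-kB median -1.65 over the ascending aorta. With so few cells, a difference of the class is not separated from another mix of its sub-clusters.

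Barcodes with at least 5 UMIs over 6 smooth muscle genes numbered 8 in the root, 26 in the ascending aorta and 33 in the arch. Of these, 7, 22 and 22 were kept, and 1, 2 and 11 failed the cell filter; the rest were removed as doublets. Among barcodes that failed the filter, those with at least 3 hemoglobin UMIs made up 18.4% in the root, 16.3% in the ascending aorta and 6.09% in the arch.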
